A study of Rattus norvegicus with 24 samples.

How the data were processed

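Transcript levels were measured by RNA sequencing in 24 libraries of rat left ventricle, 6 in each of the groups Sham, MI, Sutured patch and Microneedle patch. Per the labels' protocols, tissue of the infarct region was taken at day 7, total RNA was extracted with Trizol, and libraries were made with a NEBNext Ultra RNA kit. The deposited table holds whole-number read counts per Ensembl gene ID, 1 column per library, with no normalization and no pooling of replicates. The submitters' processing notes name HISAT2, featureCounts and the genome build rn6. The versions, the annotation release, the handling of reads that map to several places, and whether strand was used in counting are not given in the sources used here. Reads from overlapping or near-identical genes could therefore not be told apart, and a gene and an antisense partner may share counts.

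Columns were assigned to samples by the code in brackets in each sample title, and 0 columns stayed unassigned. The table held 32883 gene IDs and 0 rows without a gene. The IDs come without symbols. The table of RefSeq genes at hand, of the assembly GRCr8, holds 0 Ensembl IDs, so that 0 of the 32883 IDs could match whether or not the assembly has these genes. The files used here do not pair IDs with names and no gene is named. As a result, the 43 gene lists and the markers of other cell types fixed beforehand could not be tested (0 lists were run), and neither could a covariate built from sarcomere genes. Groups of genes are described by their behaviour across the comparisons instead.

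Total counts ranged from 5443782 (Sham replicate 5) to 14552623 (microneedle patch replicate 4). A floor of 3 counts corresponded to 0.21 to 0.24 CPM in libraries of the infarct groups and 0.26 to 0.55 CPM in Sham libraries; such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Because each Sham library was shallower than each other library, depth and the Sham group are confounded, and lowly expressed genes were measured less precisely in Sham. The labels give no sequencing or library batch, and none was used in a fit. A batch that coincided with the Sham group, if there was one, could therefore not be told apart from it.

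The test was fixed before the data were examined. Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3) with its default minimum count of 10, which left 14540 genes holding 99.6% to 99.9% of the counts of each library. Counts were scaled by TMM. All 24 libraries entered a single fit with 4 group means (20 residual degrees of freedom), with robust dispersion estimation and a robust quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison. A gene was called changed at an adjusted p below 0.05. All adjusted p-values of single genes in the text come from this edgeR test unless another tool is named. Standard errors of log2 fold changes were obtained as the absolute log2 fold change divided by the square root of the F statistic. The comparisons were MI against Sham, each patch against MI, each patch against Sham, and the microneedle against the sutured patch. The median log2 fold change of all genes was between -0.042 and 0.021 in the 6 comparisons.

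The rule for genes to print, fixed beforehand, took in each comparison the 6 called genes each way with the largest positive and negative log2 fold changes and a mean of at least 10 CPM in the higher group. It also asked for a gene symbol, a protein-coding gene and a set of named cardiac genes, which could not be applied. It was therefore limited to the first 2 IDs in each direction for the microneedle patch against MI, the comparison named by the study's title; this restriction was made after the data were seen. CPM values use TMM-scaled library sizes, and shares of counts use the total of all genes.

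Overlaps of calls between comparisons that share libraries were set beside the overlap of independent lists, beside 20 simulations of unchanged groups drawn with the fitted dispersions, and beside the values with the shared 6 libraries split 3 and 3 in each of 20 ordered ways. Shares of counts were compared with exact two-sided permutation tests over 924 splits; these share tests were chosen after the data were seen. Principal components were computed on log2 CPM with a prior count of 2.

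The edgeR test was tested on simulated data with 200 genes changed 1.5-, 2- or 4-fold. Counts for the 14540 genes were drawn independently, from the mean profile of the second-named group of each comparison for all libraries. They used the real library sizes and a single dispersion per gene for all groups. Unequal spread of the groups and variation shared across genes were therefore not simulated. For MI against Sham the test found 92.4% of the 4-fold, 38.8% of the 2-fold and 17.9% of the 1.5-fold changes. It made 10 false calls among unchanged genes (9.17% of calls). For the microneedle patch against MI the shares were 87.9%, 41.8% and 5.97%, with 6 false calls (6.25% of calls). For the sutured patch against MI they were 83.3%, 37.3% and 11.9%, with 4 false calls (4.35% of calls). For the comparison of the patches they were 84.8%, 55.2% and 11.9%, with 6 false calls (5.61% of calls). For the sutured patch against Sham they were 75.8%, 50.7% and 13.4%, with 8 false calls (7.92% of calls). For the microneedle patch against Sham they were 83.3%, 35.8% and 11.9%, with 5 false calls (5.43% of calls).

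Alternatives fixed beforehand were DESeq2 size factors within edgeR, no low-count filter, a filter of 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom with quality weights (limma 3.58.1), only the 2 groups compared, the replicate number as a block, a 2-fold minimum, and each library left out in turn. Chosen after seeing the data were thinning of all libraries to 5443782 counts, the first principal component of the residuals as a covariate, the fit without Sham replicates 4 and 5, and the effect of single libraries on the printed IDs. Each comparison was also refitted on 100 splits of its libraries, the real one included. Figures were drawn with matplotlib 3.10.9.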

Results

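RNA was sequenced from left ventricular tissue of Sprague Dawley rats, an outbred laboratory strain. Per the labels, it was taken 7 days after infarction and patch implantation from the infarct region; they do not say which part of the ventricle was taken from Sham hearts. Myocardial infarction (MI) is the death of heart muscle after its blood supply is interrupted. The 24 libraries fell into 4 groups of 6: Sham, the operated control; MI, infarct without a patch; Sutured patch, infarct with a patch fixed by sutures; and Microneedle patch, infarct with a patch that holds itself in the tissue by microneedles. The design asks how the infarct region differs from Sham tissue, whether either patch shifts the transcriptome of the infarct region, and whether the mode of fixation matters. Each library was treated as 1 replicate; the labels do not state that each came from a separate rat, so p-values measure the spread between these libraries.

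Total counts per library ranged from 12864218 to 13974505 in MI, from 12574300 to 14437712 with the sutured patch and from 13590783 to 14552623 with the microneedle patch, but from 5443782 to 11757562 in Sham. Every Sham library was therefore shallower than every library of the other groups. The number of genes with at least 1 count averaged 15515 ± 1294 (SD, n = 6) in Sham and 17238 ± 107 (SD, n = 6) in MI. Sham replicates 4 and 5 had the fewest genes, 14079 and 13635, and Sham replicate 5 also had the lowest total. The biological coefficient of variation within a group was 51.8% in Sham, 21.3% in MI, 34.0% with the sutured patch and 33.1% with the microneedle patch. No pair of libraries of 1 group agreed within sampling noise, as the lowest chi-square per degree of freedom of any pair was 15.3. The table held 32883 rat Ensembl gene IDs without gene symbols and no symbol could be paired with them here, so genes are described as groups defined by their behaviour, with 4 IDs given in full. On the first principal component, which held 44.9% of the variance, the 6 Sham libraries lay between -129 and -99.3 and the 18 libraries with an infarct between -16.1 and 70.0.

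**Figure D1:**
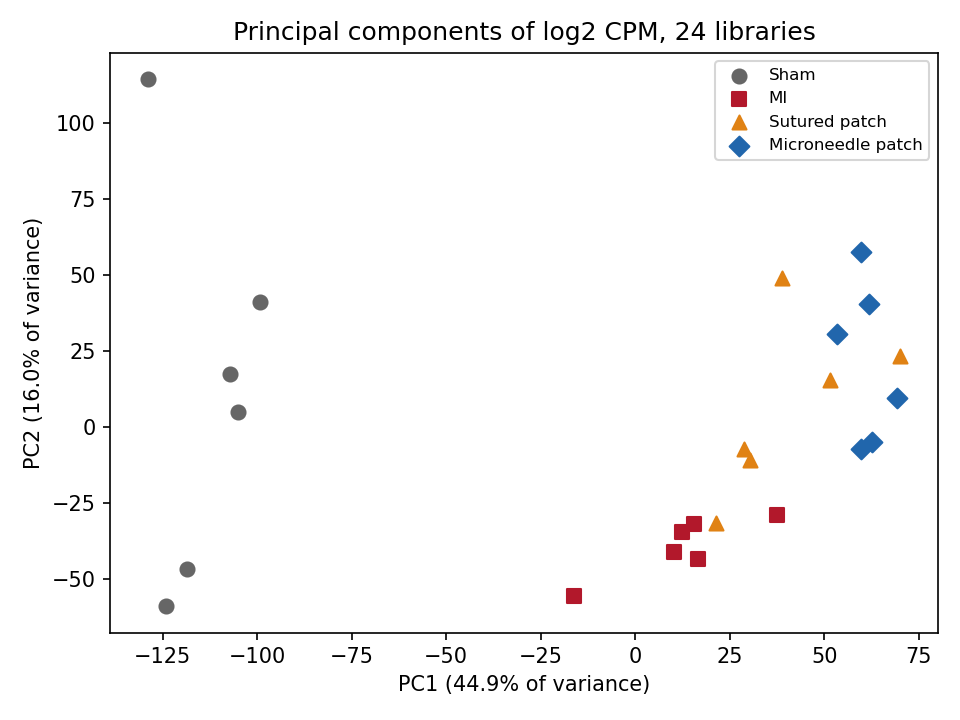
Scores of the 24 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis and 1 symbol per library, coloured by group. Sham libraries lie at or below -99.3 on the first axis and all others at or above -16.1, and Sham replicate 5 stands at 114 on the second axis.

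The tissue of MI hearts differed from Sham tissue in 6504 of the 14540 genes tested (44.7%), of which 3135 were higher and 3369 were lower in MI. The genes that rose were the smaller part of the Sham transcriptome: they held 12.9% ± 0.40 of all counts in Sham and 41.1% ± 3.81 in MI (SD, n = 6 each). The genes that fell held 48.0% ± 1.01 of the counts in Sham and 20.5% ± 2.77 in MI. Both sets of genes were selected in these libraries, so their shares differ between MI and Sham by that selection. Rises were steeper than falls, with a median log2 fold change of 1.37 among the genes that rose and -0.97 among those that fell. A change of at least 4-fold was seen for 932 genes that rose and 394 that fell. A group of 53 genes was close to absent from Sham tissue, with at most 3 counts over the 6 Sham libraries, yet averaged at least 1 CPM in MI and was called higher there.

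The MI transcriptome was also more concentrated in its 10 most abundant genes. The 100 most abundant held 26.6% ± 1.70 of counts in MI and 23.7% ± 1.84 in Sham, with overlap between the groups (24.5% in MI replicate 1, 25.5% in Sham replicate 4). The 10 most abundant genes of each library held 12.3% ± 1.75 of counts in MI against 7.44% ± 1.25 in Sham, higher in 6 of 6 MI libraries than in any Sham library (exact permutation test, two-sided p = 0.00216, the smallest that 924 splits can give; Benjamini-Hochberg adjusted p = 0.00649 over 6 comparisons of shares, all chosen after seeing the data). The calls came from edgeR's quasi-likelihood test at an adjusted p below 0.05. With all libraries thinned to the total of Sham replicate 5, an alternative chosen after seeing the data, 6151 genes were called, and 3725 of the 6504 genes had a fold change of at least 2. Without Sham replicates 4 and 5, an alternative also chosen after seeing the data, the count was 7271.

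The difference from Sham was largely shared by the 3 groups with an infarct. Of the 3135 genes higher in MI than in Sham, 2433 (77.6%) were also called higher in both patch groups, and of the 3369 lower genes 2326 (69.0%) were also called lower in both. Compared with Sham, the sutured patch group differed in 6975 genes, 3511 higher and 3464 lower. The microneedle patch group differed in 7494 genes, 3763 higher and 3731 lower. Genes called in opposite directions in MI and in a patch group, each against Sham, numbered 5 for the sutured patch and 4 for the microneedle patch.

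Because all these comparisons share the Sham libraries, fold changes of unchanged simulated groups already correlated across genes with r = 0.51 for both patches. The observed values were r = 0.90 for the sutured and r = 0.88 for the microneedle patch, with covariances of 1.66 and 1.84 against simulated covariances of 0.068 for both. With the Sham libraries split into 3 and 3 so that the comparisons shared none, the median covariance over 20 splits was 1.61 (range 1.40 to 1.66) and 1.79 (range 1.51 to 1.86). Genes are not independent replicates, so these are descriptions of the 14540 genes. A trait of all Sham libraries, such as their lower depth, would be shared by the comparisons too, and splitting Sham does not remove it. Same-direction calls numbered 5169 for the sutured and 5179 for the microneedle patch. Independent lists of these sizes would share 757 higher and 803 lower genes for the sutured patch, and 811 and 864 for the microneedle patch. Unchanged simulated groups called at most 1 gene in any comparison, so their 0 shared calls in 20 simulations were fixed beforehand and say nothing about sharing. The split libraries gave medians of 3674 and 3815 shared calls. Opposite calls then had medians of 22 (range 2 to 230) for the sutured and 16 (range 3 to 267) for the microneedle patch. Without Sham replicates 4 and 5, 7784 genes were called for the sutured and 8011 for the microneedle patch.

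**Figure D2:**
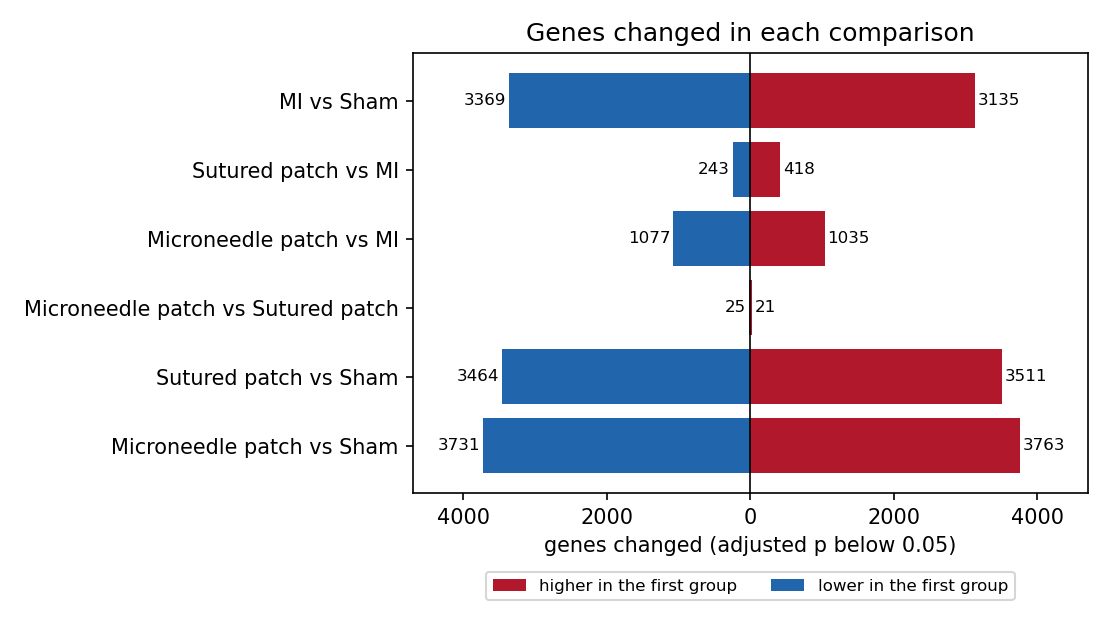
Number of genes called at an adjusted p below 0.05 in each of the 6 comparisons (horizontal axis, genes), with genes higher in the first-named group to the right of 0 and genes lower to the left. The 3 comparisons with Sham call between 6504 and 7494 genes, and the comparison of the patches calls 46.

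Fixing a patch with sutures was accompanied by 661 changed genes relative to MI alone, 418 higher and 243 lower. The 418 genes that rose held 1.35% ± 0.15 of counts in MI and 2.87% ± 0.57 with the sutured patch (SD, n = 6 each), and 1.19% ± 0.19 in Sham. The 243 genes that fell held 5.70% ± 0.47 in MI, 3.08% ± 0.43 with the patch and 2.15% ± 0.24 in Sham. Of these 243 genes, 131 (53.9%) had been higher in MI than in Sham and 40 (16.5%) lower. Among the 418 genes that rose, 164 (39.2%) had also been higher in MI than in Sham and 56 (13.4%) lower. The median log2 fold change was 1.20 for the genes that rose and -1.03 for those that fell. Shares of genes selected in a comparison differ there by that selection. MI against Sham and patch against MI also share the MI libraries, which favours opposite calls, so a return towards Sham cannot be read from these values. With the MI libraries split so that none was shared, a median of 49.9% (range 41.8 to 59.0 over splits) of the genes higher in MI went down with the sutured patch.

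In this comparison the count moved with single libraries and with the fit. It was 308, 367, 358 and 342 without MI replicates 1, 2, 4 and 5, respectively. It was 384, 418 and 328 without sutured patch replicates 3, 4 and 6, and 1408 without Sham replicate 5. DESeq2 called 1143 genes, limma-voom with quality weights 3128 and a fit of the 2 groups alone 2141, while a 2-fold minimum left 379; without Sham replicates 4 and 5, left out after seeing the data, 1715 were called, and 1725 with the first residual component as a covariate, also chosen after seeing the data.

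With the microneedle patch 2112 genes differed from MI alone, 1035 higher and 1077 lower. The genes that fell included abundant transcripts of the Sham ventricle: together they held 21.7% ± 6.32 of counts in Sham, 11.6% ± 2.71 in MI, 7.15% ± 2.39 with the sutured patch and 4.76% ± 0.86 with the microneedle patch (SD, n = 6 each). The genes that rose held 5.53% ± 0.82 in Sham, 7.63% ± 0.81 in MI, 10.8% ± 1.57 with the sutured patch and 13.03% ± 1.40 with the microneedle patch. Of the 1077 genes that fell, 532 (49.4%) had already been lower in MI than in Sham and 91 (8.45%) higher. Of the 1035 that rose, 423 (40.9%) had been higher in MI than in Sham and 118 (11.4%) lower. Falls were steeper than rises, with median log2 fold changes of -1.31 and 0.79, and 333 genes fell at least 4-fold against 99 that rose as much.

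**Figure D3:**
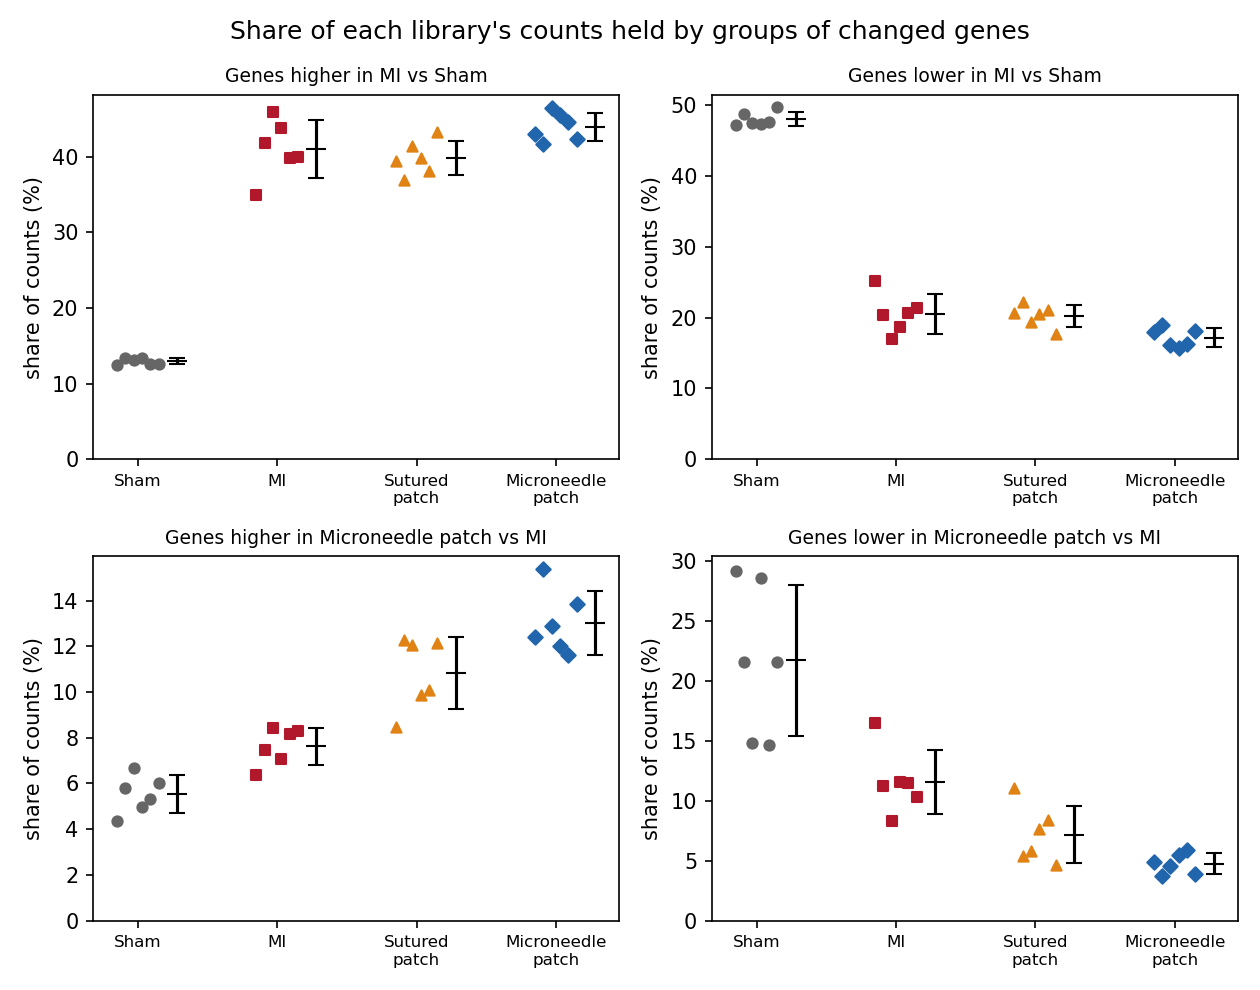
Share of all counts (vertical axes, percent) held by 4 groups of changed genes in each library, 1 symbol per library; black bars give the mean and SD of 6 libraries per group. Genes lower with the microneedle patch than in MI average 21.7% in Sham, 11.6% in MI, 7.15% with the sutured patch and 4.76% with the microneedle patch; those selected for a difference between MI and the microneedle patch differ there by selection.

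The 2 steepest falls among IDs with at least 10 CPM in the higher group were those of ENSRNOG00000042897 and ENSRNOG00000025757. ENSRNOG00000042897 averaged 10.4 ± 3.26 CPM in MI (SD, n = 6) and 0.195 ± 0.185 CPM with the microneedle patch, where the 6 libraries held 16 counts in all. Its log2 fold change was -5.67 (SE 0.77, adjusted p = 0.000186, lower in 6 of 6 libraries than in any MI library). In Sham it stood at 11.4 ± 6.85 CPM and with the sutured patch at 4.19 ± 4.79 CPM, and it did not differ between MI and Sham (adjusted p = 0.855). ENSRNOG00000025757 averaged 6171 ± 4452 CPM in Sham, 1745 ± 1063 in MI, 523 ± 582 with the sutured patch and 53.0 ± 39.2 with the microneedle patch. Its log2 fold change was -5.04 between the microneedle patch and MI (SE 0.81, adjusted p = 0.00054, lower in 6 of 6 libraries) and -1.82 between MI and Sham (SE 0.70, adjusted p = 0.0371). Its sutured patch value did not pass the test against MI (log2 fold change -1.74, SE 0.70, adjusted p = 0.167).

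The 2 steepest rises were those of ENSRNOG00000048402 and ENSRNOG00000046379, and both were uneven between libraries. ENSRNOG00000048402 averaged 0.62 ± 0.80 CPM in MI and 10.1 ± 13.7 CPM with the microneedle patch, where it ranged from 0.45 to 36.8 CPM. Its log2 fold change was 3.99 (SE 1.10, adjusted p = 0.0186, above every MI library in 4 of 6 libraries). The call was lost without microneedle patch replicate 2 (log2 fold change 2.93, adjusted p = 0.0817) and without MI replicate 1 (3.76, adjusted p = 0.0514), and the log2 fold change was 4.88 without MI replicate 5 (adjusted p = 0.015), whereas the 10 alternative settings gave adjusted p-values from 0.0128 to 0.0472. In Sham it had 3 counts over 6 libraries, and with the sutured patch it averaged 4.04 ± 5.22 CPM. ENSRNOG00000046379 averaged 1.56 ± 0.23 CPM in MI and 17.9 ± 18.7 CPM with the microneedle patch, with a range from 1.88 to 46.2 CPM. Its log2 fold change was 3.51 (SE 0.81, adjusted p = 0.00585, above every MI library in 5 of 6 libraries). Of these 5, replicate 1 was barely above, with 2.03 CPM against 1.99 CPM in MI replicate 3. Replicates 2, 4 and 5 carried most of the rise, with 46.2, 20.2 and 33.3 CPM. With limma-voom the log2 fold change of ENSRNOG00000046379 was 2.01 (adjusted p = 0.0134, from 3.11e-05 to 0.0135 over the 10 alternatives). It stood at 2.08 ± 0.70 CPM with the sutured patch and at 5.04 ± 6.98 CPM in Sham. Whether any of the 4 IDs shares reads with a near-identical or overlapping gene was not tested.

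**Figure D4:**
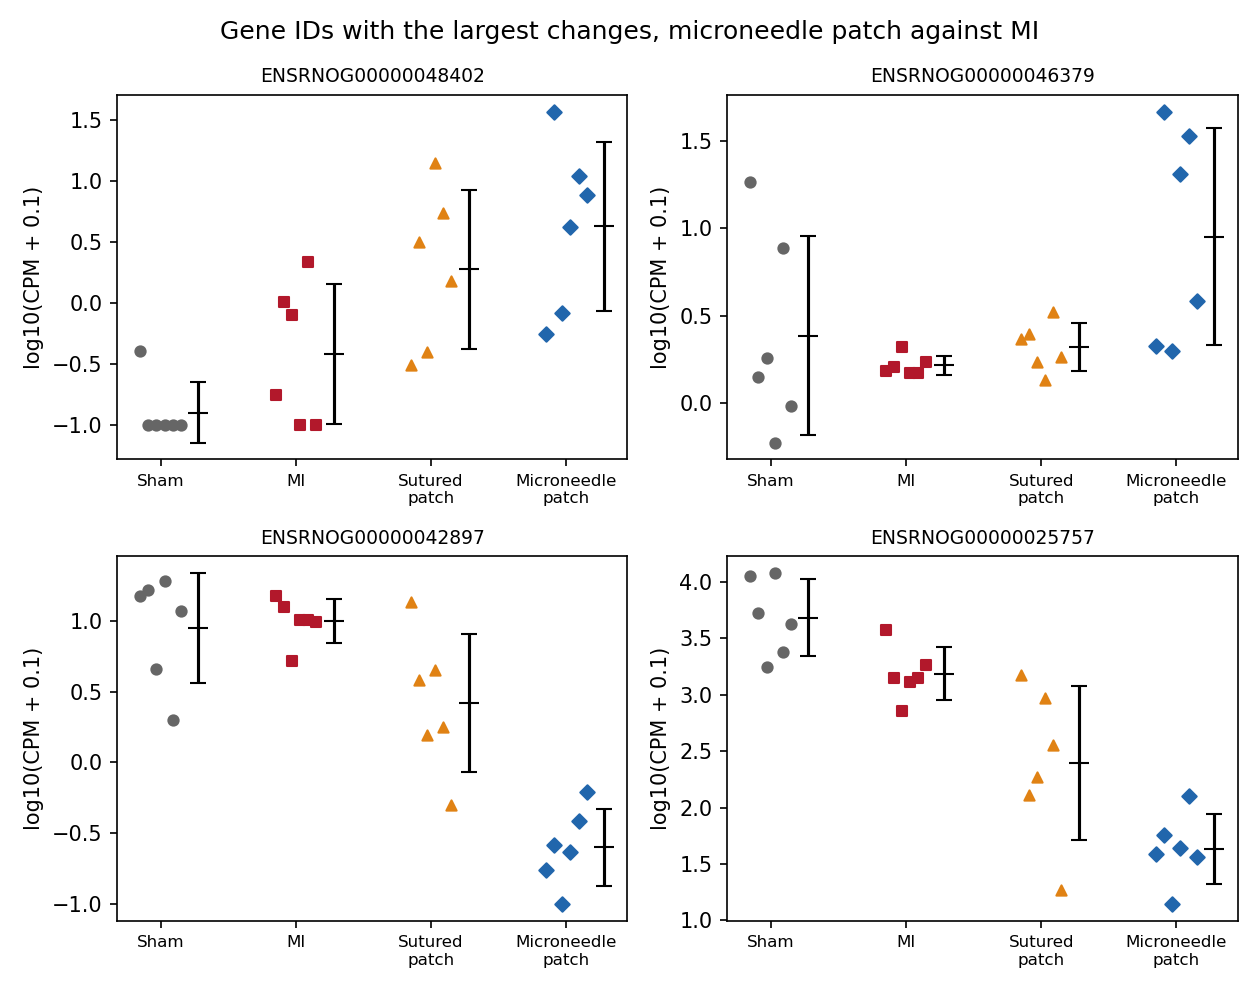
Level of the 4 gene IDs in each library (vertical axes, log10 of CPM plus 0.1), 1 symbol per library, with black bars for the mean and SD of the log10 values in 6 libraries per group. ENSRNOG00000025757 falls from an average of 6171 CPM in Sham to 53.0 CPM with the microneedle patch, and ENSRNOG00000048402 and ENSRNOG00000046379 spread widely among the microneedle patch libraries.

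The count of 2112 genes also moved with single libraries: it was 1036 without MI replicate 1, 1223 and 1266 without microneedle patch replicates 2 and 6, and 3482 without Sham replicate 5. The fit of the 2 groups alone called 4593 genes, limma-voom 5089 and a 2-fold minimum left 1071; of the alternatives chosen after seeing the data, leaving out Sham replicates 4 and 5 gave 3804 and the first residual component as a covariate gave 3602.

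Placed along the difference between MI and Sham, the microneedle patch effect was tilted towards the direction of the infarct, with many genes going the other way. The MI libraries were split into 3 and 3, so that MI against Sham and patch against MI shared no library. Over 20 such splits the slope across genes of the microneedle patch effect on the infarct effect had a median of 0.16 (range 0.075 to 0.23), and that of the sutured patch a median of 0.048 (range -0.033 to 0.12). Among genes called lower in MI than in Sham with one set of 3 libraries, the median log2 fold change of the microneedle patch against the other 3 was -0.086 (range -0.19 to 0.0065), and among those called higher it was 0.13 (range 0.032 to 0.24). The same medians for the sutured patch were -0.022 (range -0.12 to 0.078) and 0.00099 (range -0.098 to 0.10). With the microneedle patch a median of 40.2% of the genes higher in MI went down and 42.8% of the genes lower in MI went up. Whether the slopes of the patches differ was not tested. In the 86.5 genes, on median over splits, that were more than 3 log2 units lower in MI than in Sham, the microneedle patch effect had a median of -0.79 (range -1.46 to -0.27), whereas genes between 0 and 0.5 log2 units lower in MI had a median of 0.090 (range 0.078 to 0.10). In the genes more than 3 log2 units lower in MI, the sutured patch effect had a median of -0.22 with a range across 0 (-0.76 to 0.56). It lay below 0 in genes 2 to 3 log2 units lower in MI, with a median of -0.33 (range -0.60 to -0.0028). The same held in genes 1 to 2 units lower, with a median of -0.17 (range -0.28 to -0.039). In the bins of 2 to 3 and 1 to 2 units the microneedle patch medians were -0.63 (range -0.89 to -0.35) and -0.30 (range -0.43 to -0.17).

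**Figure D5:**
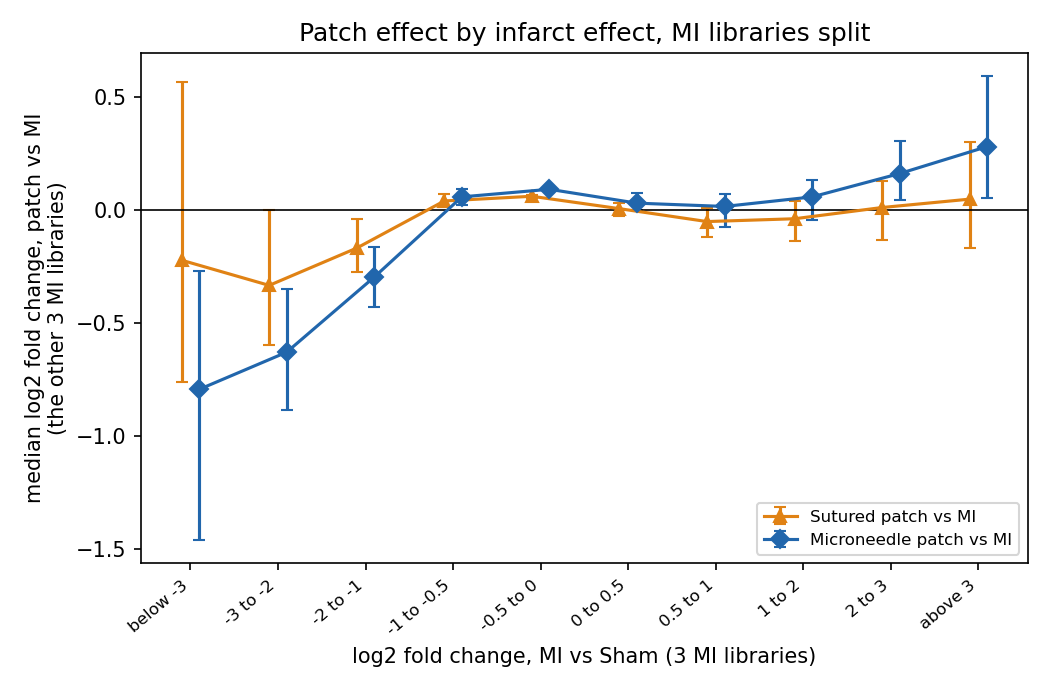
Median log2 fold change of each patch against 3 MI libraries (vertical axis), in bins of the log2 fold change between the other 3 MI libraries and Sham (horizontal axis). Points are medians over 20 splits of the MI libraries and bars span their full range, not a standard error; the microneedle patch lies below 0 in the 3 bins of genes lowest in MI and above 0 in the 2 bins of genes highest in MI.

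Genes called in opposite directions in MI against Sham and in a patch group against MI numbered 187 for the sutured patch and 209 for the microneedle patch. For the sutured patch, 131 genes rose in MI and fell with the patch, where independent lists would give 52.4, and 56 genes fell and then rose, where independent lists would give 96.9. For the microneedle patch these numbers were 91 against 232 and 118 against 240. Same-direction calls were 204 for the sutured patch (164 higher, 40 lower) and 955 for the microneedle patch (423 higher, 532 lower). Independent lists would share 90.1 and 56.3 genes for the sutured and 223 and 250 for the microneedle patch. Simulated unchanged groups, with at most 1 gene called in any comparison, gave 0 calls of either kind, which sets no chance level for these overlaps. Because MI enters the comparisons with opposite signs, their fold changes correlated in the simulations with r = -0.49 for both patches. The observed r was 0.054 for the sutured and 0.22 for the microneedle patch, with covariances of 0.044 and 0.22 against -0.065 and -0.064 in the simulations. With split MI libraries, the median covariance was 0.081 (range -0.048 to 0.22) and 0.26 (range 0.11 to 0.42), and the opposite calls had medians of 20.5 (range 15 to 50) and 24.5 (range 9 to 52). The same-direction calls then had medians of 30 (range 17 to 132) and 292.5 (range 95 to 732).

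The opposite calls moved with single libraries. For the sutured patch they numbered 105, 100, 88 and 96 without MI replicates 1, 2, 4 and 5, respectively. They numbered 112, 120, 105 and 105 without sutured patch replicates 2, 3, 4 and 6, and 369 without Sham replicate 5. For the microneedle patch they numbered 77, 122, 90 and 120 without MI replicates 1, 2, 4 and 5, respectively. They numbered 132, 70, 361 and 80 without microneedle patch replicates 1, 2, 5 and 6, and 340 and 494 without Sham replicates 4 and 5. DESeq2 gave 318 for the sutured and 365 for the microneedle patch, fits of the 2 groups alone 515 and 546, and the fit without a low-count filter 117 for the microneedle patch. Of the alternatives chosen after seeing the data, leaving out both Sham libraries gave 440 for the sutured and 520 for the microneedle patch, and the first residual component as a covariate 516 and 660.

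The patches tended to differ from MI in the same direction. Of the genes changed by each, 394 were called in the same direction with both patches, 264 higher and 130 lower, where independent lists would share 29.8 and 17.999. With the MI libraries split so that the comparisons shared none, genes called higher with the microneedle patch had the same sign with the sutured patch in a median of 96.6% of cases (range 86.2 to 100 over 20 splits), and genes called lower in 98.6% (range 94.3 to 100). The genes were called on the microneedle patch libraries, which favours larger microneedle values, so sizes are not compared between patches. Measured against the 3 MI libraries not used to call them, the median log2 fold change was 1.16 with the microneedle and 0.77 with the sutured patch for genes called higher. For genes called lower it was -2.15 with the microneedle and -0.94 with the sutured patch. Across all 14540 genes the fold changes against MI correlated with r = 0.73, where simulated unchanged groups gave 0.50, and the covariance was 0.38 against a simulated 0.064. With split MI libraries the median covariance was 0.34 (range 0.31 to 0.36). The same-direction calls then had a median of 44 (range 38 to 59), while the simulations gave 0, fixed by having almost no calls. A trait of all MI libraries would enter both comparisons, and splitting MI does not remove it. Such a trait could not be told apart from an effect that the patches share.

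The 394 shared calls became 154, 219, 210 and 203 without MI replicates 1, 2, 4 and 5, respectively. They became 223 and 216 without sutured patch replicates 3 and 6, and 868 without Sham replicate 5. Without Sham replicates 4 and 5, left out after seeing the data, there were 1043, and with the first residual component as a covariate, also chosen after seeing the data, 1143. DESeq2 gave 693 and fits of the 2 groups alone 1345.

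Compared directly, the patches differed in 46 genes, 21 higher and 25 lower with the microneedle patch. Of the 25 genes that fell, 22 (88.0%) had been lower in MI than in Sham, and they held 0.62% ± 0.092 of counts in Sham, 0.12% ± 0.034 in MI, 0.12% ± 0.022 with the sutured patch and 0.046% ± 0.0030 with the microneedle patch (SD, n = 6 each). ENSRNOG00000042897 was among them (log2 fold change -4.36, SE 0.76, adjusted p = 0.0291). Of the 21 genes that rose, 15 (71.4%) had been higher in MI than in Sham, and they held 0.20% ± 0.036 of counts with the sutured and 0.42% ± 0.064 with the microneedle patch. The median log2 fold change was 1.11 among the genes that rose and -1.90 among those that fell.

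Groups of genes defined by the contrast of MI with Sham differed between the patches too. The 3135 genes higher in MI than in Sham held 43.9% ± 1.90 of counts with the microneedle patch and 39.8% ± 2.28 with the sutured patch (SD, n = 6 each; exact permutation test, two-sided p = 0.013, Benjamini-Hochberg adjusted p = 0.0195 over 6 comparisons). In 3 of 6 microneedle patch libraries the share exceeded every sutured patch library. The 3369 genes lower in MI than in Sham held 17.2% ± 1.32 and 20.3% ± 1.55 (exact permutation test, two-sided p = 0.00866, adjusted p = 0.0173), with 3 of 6 microneedle patch libraries below every sutured patch library. In both cases these were replicates 3, 4 and 5. In MI, whose libraries helped to select the genes, the shares were 41.1% ± 3.81 and 20.5% ± 2.77. Neither patch was tested against these MI shares. The 10 most abundant genes held 12.96% ± 0.32 of counts with the microneedle and 11.4% ± 0.93 with the sutured patch, higher in 6 of 6 libraries (exact permutation test, two-sided p = 0.00216, adjusted p = 0.00649). Neither value passed the test against the 12.3% ± 1.75 of MI (exact permutation tests, two-sided p = 0.37 for the microneedle and p = 0.307 for the sutured patch, adjusted p = 0.37 and 0.369). With 6 libraries per group this does not show that they equal MI.

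The number of genes that separated the patches was not stable. With edgeR it was 0 without sutured patch replicate 4 or 5 or microneedle patch replicate 2, with 1516, 1630 and 1487 genes, respectively, at an unadjusted p below 0.05. It was 1, 12, 4 and 5 without microneedle patch replicates 1, 3, 4 and 6, and 26 without sutured patch replicate 1. It rose to 198 without sutured patch replicate 6, 83 without microneedle patch replicate 5, and 86 and 302 without Sham replicates 1 and 5. With all libraries DESeq2 called 431 genes and limma-voom 788, and the fit without a low-count filter 28. Without Sham replicates 4 and 5, left out after seeing the data, the count was 499, and with the first residual component as a covariate, also chosen after seeing the data, 399. Counts simulated with the depths of these libraries had a single spread per gene for all groups and no variation shared across genes. On them the test for this comparison found 84.8% of genes changed 4-fold, 55.2% of those changed 2-fold and 11.9% of those changed 1.5-fold. In the real libraries, whose groups differ in spread, these shares may differ.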

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

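Values that stand far from the others of their group were sought among 60 sets of 6 values, by the gap of the highest or lowest library to its neighbour over the range of the group. The gap exceeded Dixon's 95% critical value for 6 samples in 6 sets. For independent, normally distributed values chance alone gives about 1 in 20, or 3 of 60. These sets share libraries, and most of the 6 are CPM values of IDs printed for their large changes, so the 3 is no firm yardstick here. No biological explanation of these 6 values was tested.

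Sutured patch replicate 2 had 16359 genes with a count, against 17155 to 17404 in the other 5 libraries of its group (ratio 0.76). ENSRNOG00000048402 gave 3 such values: in Sham its 3 counts all fell in replicate 1 (0.30 CPM against 0 in the others, ratio 1), in the sutured patch group replicate 4 stood at 13.9 CPM against at most 5.30 (ratio 0.63), and in the microneedle patch group replicate 2 stood at 36.8 CPM against at most 10.8 (ratio 0.72). ENSRNOG00000042897 stood at 13.5 CPM in sutured patch replicate 1 against at most 4.38 in the others (ratio 0.70). ENSRNOG00000025757 stood at 3788 CPM in MI replicate 1 against at most 1834 in the others (ratio 0.64).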

How the results depend on the processing

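The direction of the counts and calls was checked under 11 alternatives for counts of genes, 8 for overlaps and 10 for each printed ID; the residual component, the thinning and the fit without Sham replicates 4 and 5 were chosen after seeing the data. The 4 printed IDs kept their direction and their call in each of their 10 alternatives, but limma-voom gave log2 fold changes of 2.01 for ENSRNOG00000046379 (3.51 with edgeR), 3.21 for ENSRNOG00000048402 (3.99) and -6.28 for ENSRNOG00000042897 (-5.67), each a move of over 1.5 times in fold. With libraries left out in turn, also chosen after seeing the data for the IDs, ENSRNOG00000048402 lost its call without MI replicate 1 (3.76) and without microneedle patch replicate 2 (2.93). The counts against Sham stayed within 1.5 times of their reported values in all alternatives but the 2-fold minimum, whose construction removes smaller changes: 3725 for MI, 4283 for the sutured and 4787 for the microneedle patch. Depth limits low genes in Sham most, and thinning to 5443782 counts moved no count by over 1.5 times.

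For the sutured patch against MI (661), DESeq2 gave 1143, limma-voom 3128, the 2 groups alone 2141, the 2-fold minimum 379, the residual component 1725 and the fit without the 2 Sham libraries 1715. For the microneedle patch against MI (2112), limma-voom gave 5089, the 2 groups alone 4593, the 2-fold minimum 1071, the residual component 3602 and the fit without the 2 Sham libraries 3804. For the microneedle against the sutured patch (46), no filter gave 28, DESeq2 431, limma-voom 788, the residual component 399 and the fit without the 2 Sham libraries 499. For opposite calls of the sutured patch (187), DESeq2 gave 318, the 2 groups alone 515, the residual component 516 and the fit without the 2 Sham libraries 440. For opposite calls of the microneedle patch (209), no filter gave 117, DESeq2 365, the 2 groups alone 546, the residual component 660 and the fit without the 2 Sham libraries 520. For same-direction calls of both patches (394), DESeq2 gave 693, the 2 groups alone 1345, the residual component 1143 and the fit without the 2 Sham libraries 1043. Of the genes that differed between the patches, 45.7% were higher with the microneedle patch, against 63.1% with limma-voom and 58.6% with the 2 groups alone. Of the settings with over 20 calls that left out 1 library, those without microneedle patch replicate 5 (67.5%) and sutured patch replicates 1 (23.1%) and 6 (29.3%) moved this share by over 10 points. For the sutured patch against MI it was 63.2%, and 50.9% with limma-voom, and for the microneedle patch against MI 49.0%, and 33.2% with the 2-fold minimum. Sham libraries are outside the comparisons between infarct groups, yet leaving 2 out raised those counts. They act there only through the shared fit: its filter, its scaling and its single spread per gene over all groups. Within groups the biological coefficient of variation was 51.8% in Sham and 21.3% in MI. How much each step contributed was not tested. Apart from this route and the 2-fold minimum, the cause was not tested.

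With 1 library left out in turn, counts ranged from 5825 to 7178 for MI against Sham, 308 to 1408 for the sutured and 1036 to 3482 for the microneedle patch against MI, 0 to 302 between the patches, and 6477 to 7774 and 7139 to 8038 for the patches against Sham. Opposite calls ranged from 88 to 369 for the sutured and 70 to 494 for the microneedle patch, and same-direction calls from 154 to 868. The cause was not tested.

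Libraries with the same replicate number were not shown to be paired: over 36 pairs of different groups the correlation of their deviations from the group means ranged from -0.14 to 0.44 (median 0.10, against -0.031 for 180 pairs with other numbers). It was over 0.1 in 19 of the 36 pairs, and 9 of 24 libraries correlated best with their own number, where chance gives 4; as a hint from the data, this leaves a partial link open. With the replicate number as a block, 159 genes differed between the patches, opposite calls of the microneedle patch numbered 337 and same-direction calls 596; the other counts stayed within 1.5 times.

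Not run, for want of gene symbols, were the list tests and their alternatives, the covariate of sarcomere genes in the 3 comparisons of groups with an infarct, and the fixed set of named genes.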

Other observations

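Chosen after the results were seen were the test with the same library left out of both comparisons and the test against the Sham axis, and, after the data were seen, the thinning and the fit without Sham replicates 4 and 5. A few genes were present in 1 infarct group and nearly absent from another: 4 genes with at most 3 counts over the 6 MI libraries were called higher with the sutured patch at a mean of at least 1 CPM, and 2 with the microneedle patch. In the reverse sense, 2 genes nearly absent with the microneedle patch were called against MI, and 1 against the sutured patch.

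Other splits of the libraries were refitted for each comparison, 100 splits each with the real one included. For MI against Sham 1 of 100 splits gave as many genes as the real 6504 (highest other 3997). For the sutured patch against Sham 1 gave 6975 (highest other 3572), and for the microneedle patch against Sham 1 gave 7494 (highest other 3179). Against MI, 1 of 100 splits reached 661 for the sutured patch (highest other 272) and 1 reached 2112 for the microneedle patch (highest other 1). These shares met the rule set beforehand against chance. As 1 of 100 is the smallest share such splits can give, they make chance unlikely for these counts but do not exclude it. For overlaps of calls these splits decide nothing, because a split without calls against MI fixes the overlap at 0. Only 3 of the 99 other splits called any gene for the sutured and 1 for the microneedle patch, and 0 of 99 other regroupings of the 18 infarct libraries called genes with both patches. So chance is left open by these splits for the opposite calls of the sutured (1 of 100 reached 187, highest other 27) and microneedle patch (1 reached 209, highest other 0) and for the same-direction calls (1 reached 394, highest other 0). For the microneedle against the sutured patch 3 of 100 splits reached 46 genes, the real one included, a share that met the rule set beforehand. The other splits among them called 157 and 696 genes, several times the real count, so chance stays open for the count of 46. Such counts point to a structure of the samples whose cause was not tested.

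More genes differed from MI with the microneedle patch (2112) than with the sutured patch (661), and library depth was argued against, since thinned to equal totals the counts still stood in a ratio of 3.06. For a single library, the test set beforehand came out as that explanation predicts, with the lowest microneedle count at 0.74 times the highest sutured count, under its bound of 1; it was ill-posed, as these counts come from fits that leave out different libraries. With the same library left out of both, a test chosen afterwards, the lowest ratio over 24 libraries was 1.69, which argues against it. Chance assignment of the 12 patch libraries stays open: 53 of 100 splits gave counts against MI at least as far apart as the real ratio of 3.20, with a highest other ratio of 29.8. The excess of the microneedle count is therefore not shown to come from the type of patch, which stays open as the biological explanation.

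The large difference between MI and Sham (6504 genes) coincides with lower totals in Sham and with the few genes detected in Sham replicates 4 and 5. Thinned to equal totals, the count was 0.95 times the reported count, and without the 2 Sham libraries it was 1.12 times, so neither accounts for it. The difference between the MI and Sham libraries was itself tested. Its source was not: the infarct, which the design names, cannot be told apart here from a batch that coincided with Sham, if there was one.

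Within both patch groups the libraries spread along a common axis, which held 37.0% of the residual variance of the 12 libraries; across genes, the axes computed in each patch group alone correlated with an absolute r of 0.53. Its score and the total count gave a Spearman rho of 0.20 (permutation p = 0.539) and a Pearson r of 0.097 (permutation p = 0.76; 0.45 without the 2 libraries farthest from the median total); the rho lies under the bound of 0.3 set beforehand against depth, but 12 libraries are too few to exclude it. A varying degree of the difference between infarcted and Sham tissue in the sampled pieces may contribute: across genes, the axis correlated with the MI minus Sham fold change with r = 0.19 (0.17 to 0.23 with 1 library left out), 0.26 in the microneedle and 0.014 in the sutured patch group, between the bounds set beforehand for and against it. A source present in all hearts would show in Sham, where the absolute r with the main residual axis was 0.092 (0.0094 to 0.38 with 1 library left out), but 0.21 for the sutured and 0.0036 for the microneedle patch libraries alone, and 0.18 between the patch and MI axes. A link by replicate number, left open above, was not tested for this axis. Replicate 2 scored -61.5 with the sutured and -60.3 with the microneedle patch, and replicates 4, 5 and 6 also had the same sign in both groups. Replicates 1 and 3 had opposite signs, with 35.9 and -24.3 for replicate 1. These explanations cannot be told apart here.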
